A study of Mus musculus with 14 samples.

How the data were processed

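RNA of 14 cultures was measured on Affymetrix whole-transcript arrays. Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled cDNA was made from 100 ng by the manufacturer's whole-transcript assay. The authors deposited 1 value per probe and array. Per the submitters' processing notes these came from RMA, which in its standard form corrects background, quantile-normalizes between arrays and summarises probes, and Partek. Their versions are not given in the sources used here. The deposited values were taken as log2 signals, a scale read from the values (from 0.72 to 14.1, with medians near 5) and from the usual output of RMA. RMA compresses differences of weak genes, so folds of genes near the bottom of the range can be understated. The signal of the array's background probes was not used here.

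The table held 28853 probes. By the platform annotation, 21789 had 1 gene symbol, 1621 several and 5443 none listed; symbols were updated through Entrez identifiers with the RefSeq gene table of mouse assembly GRCm38.p6, in which 19856 genes were found. A gene was represented by its probe with the highest mean, which gave 19938 genes, 999 of them with several probes. No gene was named from a probe with several symbols, and Trp53 and Cdkn1a, which had no probe of their own, were not analysed here.

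Arrays were grouped by the labels: SKO or GFP virus, with or without vitamin C, and the day. Each day gives 1 array with and 1 without vitamin C, so the labels pair them by day. As a check, deviations from the mean of each arm correlated across genes between the paired arrays, with Pearson r between 0.248 (day 6) and 0.677 (day 3). On days 6 and 8 the treated array correlated better with an untreated array of another day than with its own partner. No values were normalized again for the results given first. All gene tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The vitamin C test used the 12 SKO arrays with the day as a factor (5 residual degrees of freedom), and the day tests used the same fit. The slope of the vitamin C difference per day left 4 residual degrees of freedom. SKO against GFP used all 14 arrays (6 residual degrees of freedom), as did the difference of the vitamin C effect between GFP and SKO cells (5). Gene lists fixed before the data were examined (23 lists, 642 of 692 genes measured) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, and adjusted over the lists. Daily list means and the position along the time course were tested by exact sign flips over the 6 days (64 patterns). The position was the slope through the origin of a day's vitamin C difference on the per-gene change per day fitted to the other days. That change was fitted to the mean of the treated and untreated arrays of each day.

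Named genes followed a rule fixed before the data were examined: per comparison, the 12 higher and 12 lower genes of largest difference among those past the threshold with 1 direction on all 6 days (vitamin C) or in both arms (day and virus), or the 6 largest where fewer passed. Up to 4 members of each list and a fixed set of reprogramming genes were added. Clone names, predicted genes, receptor clusters, histone genes and small RNAs were counted and not named.

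On simulated data with 200 of 19938 genes changed, the vitamin C test recovered 66% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, with 6.15% false calls. For day 10 against day 3 it recovered 10% and 92%, for SKO against GFP 8% and 98%, for any day 6% and 84%, for the slope (change over the whole course) 2% and 16%, and for GFP against SKO 0% and 24%. False calls were 5.03%, 8.43%, 3.97%, 11% and 4.42% in the same order. The simulated noise was independent between genes and arrays, with each gene's spread taken from the vitamin C fit. For the vitamin C test the simulated difference was equal on all days. Real genes vary together and their differences vary between days, so these rates may not carry over to the data. A simulated lead of 1 day along the time course was measured as 0.783 days.

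Alternatives were quantile normalization, median centring, leaving out the 6646 genes with the lowest mean signal (below 4.54), an intensity trend or robust variances in eBayes, array weights, the mean of a gene's probes, a minimum of 1.5-fold, leaving out each day or array, and other codings of the day. Alternatives added after the data were seen were day sets, day 4 or day 5 as the base, SKO day 3 alone against the GFP pair, and the alternation score as a covariate. Random lists matched on mean signal (10000 lists, 50 signal bins) served as the comparison for list means. Their genes were drawn singly, so the percentiles do not allow for members of a list that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.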

Results

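Gene expression was measured in mouse embryonic fibroblasts (MEFs, primary cells grown from mouse embryos) that carried retroviruses for 3 transcription factors, Sox2, Klf4 and Oct4 (SKO; Oct4 is encoded by Pou5f1), or a virus for green fluorescent protein (GFP) as a control. The 3 factors are used to reprogram fibroblasts into pluripotent cells. From day 2 the cells were kept in embryonic stem cell medium with 50 µg/ml vitamin C or without it. SKO cells were lysed on days 3, 4, 5, 6, 8 and 10 and GFP cells on day 3, with 1 array for each condition and day: 6 arrays of SKO cells with vitamin C, 6 of SKO cells without it, and 1 GFP array of each kind. No condition and day had a replicate, so the number of arrays limits the precision. The error in the tests is the variation of the vitamin C difference between days of this 1 time course, and the p-values say nothing about variation between independent cultures.

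The medians of the 14 arrays were close, from 5.19 to 5.28 on the log2 scale. Interquartile ranges went from 3.04 (treated SKO, day 4) to 3.33 (treated SKO, day 8). The 2 widest were those of treated SKO cells on days 6 (3.30) and 8 (3.33), against 3.16 in untreated SKO cells on both days. The first principal component (32.8% of the variance) had the GFP arrays at one end (-58.4 and -55.5) and the day 10 SKO arrays at the other (36.7 and 41.1). The second (20.4%) set day 3 (-41.7 and -42.9) and day 5 (-28.1 and -18.8) of the SKO cells apart from day 4 (5.24 and 11.5) and day 6 (7.68 and 32.1). Day 10 lay between them on this component (-3.62 and 0.008), so its place with days 3 and 5 rests on the score described below. An alternation was computed per gene from days 3 to 6 of the SKO cells, in a form that removes a straight trend over these days. It averages the height of day 4 above the mean of days 3 and 5 and the depth of day 5 below the mean of days 4 and 6. It was positive for 1302 genes and negative for 1184 (limma, adjusted p under 0.05). Among the genes with a positive alternation were Pom121, a nuclear pore gene (1.37 on the log2 scale), and Cic (1.37). Among those with a negative one were Atp5mpl (-1.21) and Psmb4, a proteasome subunit gene (-0.93). These 4 genes were chosen after their values were seen. An alternation score was the mean of the 500 genes with the largest alternation, each centred on its mean and signed by its direction. This score was between -0.56 and -0.45 in the SKO arrays of days 3, 5 and 10. It was 0.43 and 0.46 on day 4, 0.13 and 0.46 on day 6, 0.47 and 0.08 on day 8, and 0.38 and 0.47 in the GFP arrays of day 3. Days 3 to 6 of the SKO cells were split by construction, since the genes of the score were chosen on them, whereas days 8 and 10 and the GFP arrays were not used to choose the genes. The GFP and SKO arrays of day 3 had opposite signs. Values within days 3, 5 and 10 and within days 4, 6 and 8 stand beside the comparisons below. This division of the days was chosen after the data were seen.

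**Figure D1:**
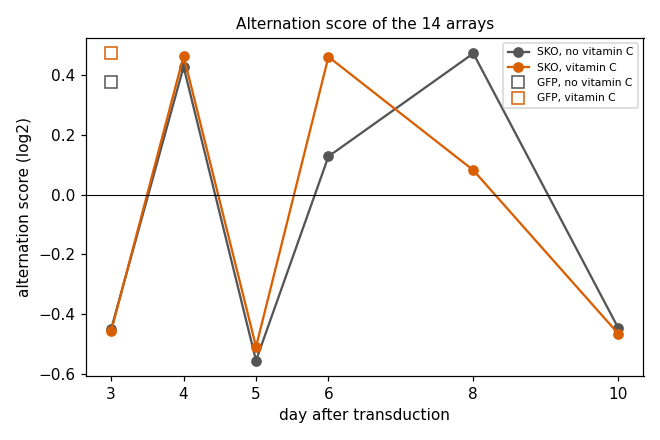
Alternation score (log2, vertical axis) of each of the 14 arrays against the day after transduction (horizontal axis); circles are SKO arrays, open squares GFP arrays, orange with and grey without vitamin C. Days 3, 5 and 10 of the SKO cells lie below -0.4, and the GFP arrays of day 3 lie at 0.38 and 0.47.

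SKO cells were compared with GFP cells on day 3, to see what the 3 factors had changed early. For the 3 factors themselves, here and below, viral transcripts were not told apart from those of the cells' own genes. The transduced factors were higher in SKO cells: Pou5f1 by 7.17 ± 0.17 (SE; log2, 145-fold, adjusted p = 2.09e-11), Klf4 by 1.01 ± 0.17 (2.02-fold) and Sox2 by 0.60 ± 0.18 (1.52-fold, adjusted p = 0.0337). Among the other genes the largest rises were in Akr1c18, a steroid dehydrogenase gene (57.0-fold), Sostdc1, a secreted antagonist of BMP and Wnt signals (45.7-fold), Crym (21.8-fold), Tmem229b (12.9-fold), Aldh3a1 (10.5-fold), Gna14 (10.4-fold), Ceacam1 (9.39-fold), Pcolce2 (8.29-fold), Anxa10 (8.00-fold), P2ry1 (7.68-fold), Mfsd6 (7.37-fold) and Scg5 (7.31-fold). The largest falls were in the interferon-induced Ifit1 (7.05-fold), Dpt, a matrix protein gene of connective tissue (6.89-fold), Anpep (6.63-fold), Igfbp5 (6.45-fold), Enpep (5.87-fold), Cdh3 (5.79-fold), Igfbp2 (5.75-fold), Ogn (5.69-fold), Slc40a1 (5.57-fold), Dlk1 (5.50-fold), Iigp1 (5.45-fold) and Sned1 (5.41-fold). Myc was 1.87-fold higher, and Thy1, a fibroblast surface marker, was 2.36-fold lower, Tet3 2.07-fold, Tet1 1.92-fold, Cdkn2a 1.66-fold, Cdkn2b 1.52-fold and Col1a1 1.48-fold lower. Nanog, a pluripotency gene, differed by 0.02 ± 0.31 and Epcam by -0.08 ± 0.20, neither past the threshold.

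Cell cycle genes rose together: 40 of 43 were higher in SKO cells and 0 lower, with a mean of 1.02, such as Rrm2 (4.11-fold), Bub1 (3.33-fold), Ncapg (3.31-fold) and Kif11 (2.72-fold; camera adjusted p = 6.51e-30, and 0.203 with an estimated correlation). Of 33 collagen and other matrix genes 18 fell and 1 rose, with Ogn, Lum (3.77-fold), Fbln1 (2.73-fold) and Col5a1 (2.43-fold) falling most (adjusted p = 1.21e-07, and 0.258 with an estimated correlation). Of 39 fibroblast and mesenchymal genes 20 fell and 3 rose. Loxl1 fell 3.14-fold and Meox1 2.88-fold, while Meox2 rose 6.55-fold (adjusted p = 5.62e-07, and 0.258 with an estimated correlation). Of 36 senescence and secretory genes 14 fell, Cxcl12 by 5.22-fold and Mmp13 by 4.57-fold, and 7 rose (adjusted p = 0.0124, and 0.258 with an estimated correlation). Of 23 collagen modification genes 11 fell and 1, Pcolce2, rose (adjusted p = 0.000183, and 0.258 with an estimated correlation). Of 36 interferon response genes 13 fell and 0 rose, with a mean of -0.94 (adjusted p = 1.63e-07, and 0.543 with an estimated correlation). The mean log2 signal of this list was 5.22 in untreated and 6.54 in vitamin C-treated GFP cells, against 4.91 and 4.96 in SKO cells. Markers of other cell types that passed singly included Tek, an endothelial receptor gene (6.32-fold higher), Hbb-y, an embryonic globin gene (5.61-fold higher), Gap43 (4.50-fold higher), Stmn2 (4.34-fold higher) and Des, a muscle filament gene (3.59-fold lower), without a call for the endothelial, erythroid, neural or skeletal muscle list (adjusted p between 0.330 and 0.549).

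In all, 1838 genes were higher and 1681 lower in SKO cells among 19938 tested (limma, adjusted p under 0.05, 2 arrays against 2). The 2 sets of arrays lay on opposite sides of the alternation score. Compared with day 4 of the SKO cells, which lay on the side of the GFP arrays, 972 genes were higher and 579 lower; 34 of the 43 cell cycle genes were higher (mean 0.73), and 12 matrix, 17 fibroblast and 6 interferon response genes were lower. Against day 4, Pou5f1 was higher by 8.09, Sostdc1 by 5.91 and Crym by 4.81, whereas Thy1 (-0.64, adjusted p = 0.239), Col1a1 (-0.49, adjusted p = 0.0914), Cdkn2a (-0.64, adjusted p = 0.108) and Tet3 (-0.04, adjusted p = 0.964) no longer passed. With the score as a covariate, which nearly follows this contrast, 17 genes passed and the fitted differences of Thy1, Col1a1 and Tet3 turned positive. Without single arrays the count was 1558 (treated GFP), 2053 (untreated SKO of day 3) and 1298 (treated SKO of day 3).

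The time course asked how SKO cells changed from day 3 to day 10. The largest rises were in Trh, the thyrotropin-releasing hormone gene, by 5.16 ± 0.41 (SE; 35.7-fold), Lbp, a lipopolysaccharide-binding protein gene (29.7-fold), Rnase1 (23.3-fold), Tac2 (15.5-fold), Avil (13.7-fold), Fbxo15, a gene of embryonic stem cells (13.4-fold), Dpp6 (13.0-fold; 1 of its 2 probes went the other way), Olfml1 (12.9-fold), Frem2 (12.6-fold), Acsbg1 (12.3-fold), Ifi203 (12.2-fold) and Mpzl2 (by 3.59 on the log2 scale). The largest falls were in Cnn1, a calponin gene (7.47-fold), Anxa10 (6.18-fold), Tspan2 (4.08-fold), Myl9 (4.06-fold), Grb14 (3.84-fold), Slc38a4 (3.81-fold), Tagln (3.75-fold), Phgdh, of serine synthesis (3.72-fold), Acta1, a skeletal muscle actin gene (3.57-fold), Tpm2 (3.52-fold), Pdlim1 (3.50-fold) and Prkar2b (3.50-fold). Sox2 rose by 0.92 ± 0.17 and Pou5f1 by 0.70 ± 0.17, but Pou5f1 stood at -0.22 against day 4 (adjusted p = 0.442). Klf4 differed by 0.12 ± 0.17, which did not pass.

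Of 41 pluripotency genes 14 rose and 0 fell. They included Tfcp2l1 (6.67-fold), L1td1 (3.25-fold), Gdf3 (2.67-fold), Nanog (2.24-fold) and Tet1 (1.64-fold; camera adjusted p = 2.54e-07, and 0.0410 with an estimated correlation). Of 32 epithelial genes 8 rose and 1 fell, with Epcam, an epithelial adhesion molecule, 7.51-fold, Spint2 4.11-fold, Ocln, a tight junction gene, 3.76-fold, St14 2.61-fold and Cdh1, encoding E-cadherin, 2.32-fold higher (adjusted p = 4.36e-05, and 0.168 with an estimated correlation). Cell cycle genes fell, 37 of 43 with a mean of -0.85, such as Cdca8 (2.45-fold), Prc1 (2.41-fold), Bub1 (2.40-fold) and Tpx2 (2.38-fold; adjusted p = 1.57e-28, and 0.0415 with an estimated correlation). Of 36 p53 targets 19 fell and 3 rose; Cd80 fell 3.07-fold, Eda2r 2.27-fold and Gtse1, which is expressed in G2 and S phase, 2.23-fold, while Sesn1 rose 2.08-fold (adjusted p = 5.24e-07, and 0.0442 with an estimated correlation). Of 36 interferon response genes 27 rose and 0 fell, with a mean of 1.52, such as Oas2 (10.8-fold), Gbp3 (9.03-fold), Oasl2 (8.46-fold) and Ifit1 (7.12-fold; adjusted p = 1.40e-17, and 0.225 with an estimated correlation). Of 23 macrophage markers 15 rose and 0 fell, with a mean of 1.06, among them Mrc1 (6.85-fold), Lyz2 (6.16-fold), Mpeg1 (4.14-fold) and Ctss (3.32-fold; adjusted p = 1.49e-14, and 0.0410 with an estimated correlation). Macrophage markers and interferon response genes were thus higher on the same arrays of day 10.

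Fibroblast and mesenchymal genes were divided, with 11 of 39 lower, led by Cnn1 and Tagln, and 4 higher, led by Lum (4.67-fold) and Dcn (4.29-fold; adjusted p = 0.00354, and 0.234 with an estimated correlation). Of 23 collagen modification genes 10 fell and 1 rose, with P4ha2 2.22-fold, Lox 1.99-fold, Loxl3 1.84-fold and P4ha3 1.73-fold lower (adjusted p = 2.07e-05, and 0.168 with an estimated correlation). Of 20 cholesterol synthesis genes 10 fell and 0 rose, led by Idi1 (1.87-fold) and Nsdhl (1.76-fold; adjusted p = 8.12e-06, and 0.250 with an estimated correlation). Of 30 unfolded protein response genes 4 fell, among them Slc7a5 (3.13-fold) and Asns (2.56-fold), and 1 rose (adjusted p = 0.000570, and 0.0522 with an estimated correlation). The list of 2-oxoglutarate dioxygenases of chromatin and nucleic acids also held the HIF hydroxylase genes Egln1, Egln2, Egln3 and Hif1an. Of its 34 genes 7 rose, among them Tet2 (3.05-fold) and Kdm7a (2.76-fold), and 1 fell (adjusted p = 0.00204, and 0.178 with an estimated correlation).

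From day 3 to day 10, 1306 genes rose and 1124 fell (limma, adjusted p under 0.05, 2 arrays against 2); after centring each array on its median the split was 1115 and 1482. Within days 3, 5 and 10, 1196 genes rose and 1012 fell, with 37 cell cycle genes lower and 26 interferon response, 15 macrophage and 10 pluripotency genes higher. Without 1 array the count was 1511 (untreated day 3), 1253 (untreated day 10), 964 (treated day 3) and 1315 (treated day 10). Against day 5 it was 345, whereas against day 4 it was 3182 (1566 higher, 1616 lower). Over all 6 days 3773 genes differed between any days (F test), with Slc7a3, an amino acid transporter gene, also among the 12 of widest range (12.4-fold between its lowest and highest day). That count crosses the alternation: it was 1232 within days 3, 5 and 10 and 175 within days 4, 6 and 8, and 1991 without day 3 and 2382 without day 10.

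The central comparison was SKO cells with vitamin C against SKO cells without it on the same day. The genes highest with vitamin C on all 6 days were Kng2, a kininogen gene, by 1.85 ± 0.22 (SE; log2, 3.60-fold, 6 day pairs, adjusted p = 0.00587), the interferon-induced Rtp4 (3.35-fold), Ifit3 (3.26-fold) and Oasl2 (3.14-fold), Entpd1 (2.95-fold), Fetub (2.80-fold), the chemokine gene Ccl8 (2.79-fold), Tyrp1 (2.74-fold), As3mt, an arsenic methyltransferase gene (2.60-fold, adjusted p = 0.000663), Gbp3 (2.57-fold), Avil (2.53-fold) and Xaf1 (2.46-fold). The genes lowest with vitamin C were Anxa10 (2.32-fold), Aldh1l2, of mitochondrial folate metabolism (2.22-fold), Pcdh10 (1.94-fold), Trib3, a stress-induced pseudokinase gene (1.90-fold), P4ha1, Mamld1 (1.84-fold), Gpr165 (1.81-fold), Ncam2 (1.78-fold), Gnai1 (1.74-fold), Tmeff2 (1.74-fold), Hapln1 (1.73-fold) and Tacr3 (1.70-fold). P4ha1 and P4ha2 encode the catalytic subunits of collagen prolyl 4-hydroxylase, an enzyme that uses vitamin C; they were 1.86-fold (-0.90 ± 0.11) and 1.51-fold (-0.59 ± 0.10) lower. The P4ha1 difference was between -1.39 and -0.60 on each of the 6 days.

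The transduced factors did not pass: Pou5f1 differed by -0.08 ± 0.10, Sox2 by 0.10 ± 0.10 and Klf4 by -0.09 ± 0.10. In the pluripotency list 2 genes rose, Tfcp2l1 (2.03-fold) and L1td1 (1.45-fold), of 41 (mean 0.13; camera adjusted p = 0.0172, and 0.244 with an estimated correlation). Nanog was 0.64 ± 0.18 higher over the 6 days, which did not pass (adjusted p = 0.139); its log2 signal was 6.49 and 7.35 with vitamin C on days 8 and 10 against 5.43 and 5.70 without. Epcam (0.43 ± 0.11, adjusted p = 0.123) and Cdh1 (0.25 ± 0.12, adjusted p = 0.494) did not pass, nor did any of the 32 epithelial genes (adjusted p of the list 0.103). When adjusted over each list alone, 7 pluripotency genes were higher and 0 lower, and 3 epithelial genes were higher and 0 lower. Myc, Cdkn2a, Cdkn2b, Kdm2a, Kdm2b, Tet1 (1 of whose 3 probes went the other way), Tet2, Tet3, Thy1, Col1a1 and the vitamin C transporter genes Slc23a1 and Slc23a2 lay between -0.20 and 0.15 and did not pass.

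**Figure D2:**
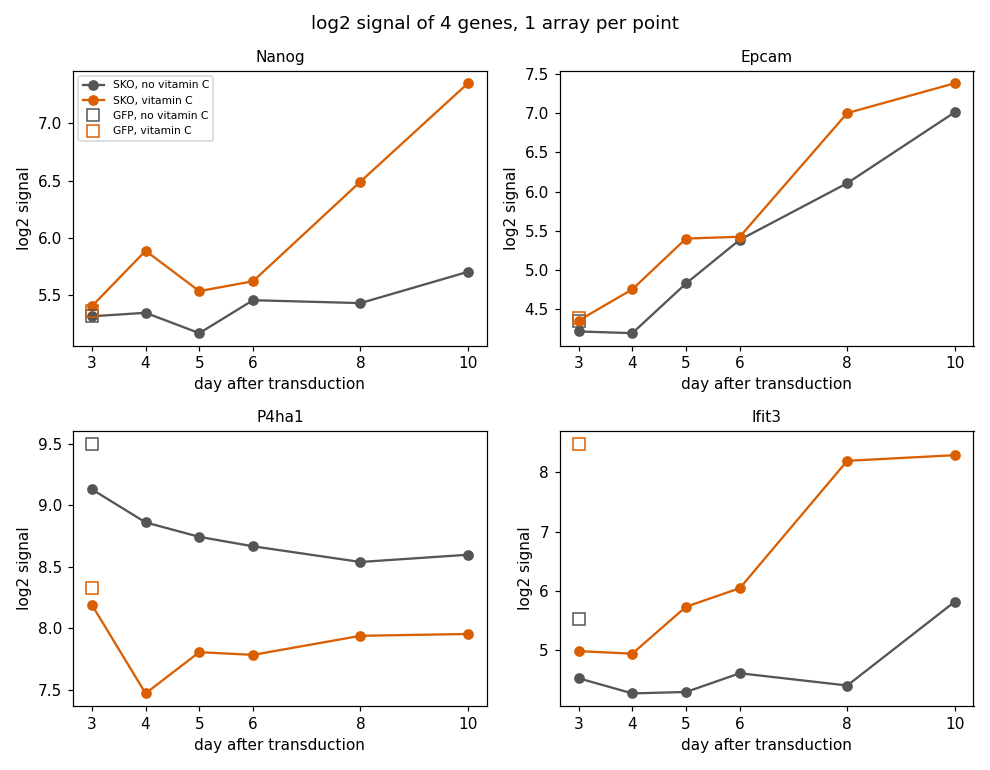
log2 signal (vertical axis) of Nanog, Epcam, P4ha1 and Ifit3 on each array against the day after transduction (horizontal axis); circles joined by lines are SKO cells, open squares GFP cells, orange with and grey without vitamin C. Nanog reached 7.35 with vitamin C on day 10 against 5.70 without, and P4ha1 was lower with vitamin C on every day; 1 array stands behind each point.

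Interferon response genes were higher with vitamin C: 13 of 36 passed, all higher, and 32 passed when adjusted over the list alone. The list mean was 0.86 (camera adjusted p = 1.31e-32, and 0.244 with an estimated correlation), and Oas2 was 2.92-fold higher. The daily difference of the list mean was 0.05 on day 3, 0.32 on day 4, 0.78 on day 5, 1.26 on day 6, 1.71 on day 8 and 1.02 on day 10 (mean 0.86 ± 0.61, SD over 6 days). Macrophage markers, which also rose with time, differed by 0.04 ± 0.11 between the arms, with 0 of 23 passing (adjusted p = 0.514).

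Unfolded protein response and amino acid stress genes were lower with vitamin C, with Trib3 and Phgdh (1.46-fold) past the test among 30, 8 lower when adjusted over the list alone, and a mean of -0.22 ± 0.05 (SD over 6 days; adjusted p = 3.97e-09, and 0.0268 with an estimated correlation). This was the only one of the 23 lists whose vitamin C call held with an estimated correlation. HIF targets, genes induced by the hypoxia-inducible factor, had a mean of -0.13 ± 0.10: P4ha1 and P4ha2 passed among 37, and 11 were lower and 2 higher when adjusted over the list alone (adjusted p = 0.000936, and 0.434 with an estimated correlation). Of 23 collagen modification genes P4ha1 and P4ha2, shared with the HIF list, were the 2 that passed (mean -0.17; adjusted p = 3.79e-05, and 0.244 with an estimated correlation). In the neural list 2 markers were lower, Syt1 (1.41-fold) and Tubb3 (1.39-fold), of 24 (mean -0.12; adjusted p = 0.0117, and 0.358 with an estimated correlation).

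Further lists had a call with the preset correlation, although few or none of their members passed. The cell cycle mean was 0.08 with 0 of 43 past the test (adjusted p = 0.000936, and 0.508 with an estimated correlation). The cholesterol synthesis mean was 0.08 with 0 of 20 (adjusted p = 0.0315, and 0.616 with an estimated correlation). The fibroblast mean was -0.06, although the 1 member that passed, Lum, was 1.80-fold higher (adjusted p = 0.0172, and 0.501 with an estimated correlation). In lists without a call, Lum was higher and Tnc (1.53-fold) lower among matrix genes, and Ccl8 (2.79-fold) and Csf1 (1.48-fold) were higher among secretory factors. So were the single genes that passed in the endothelial, adipocyte, keratinocyte and early endoderm lists, Tek (1.49-fold higher), Car3 (1.69-fold higher), Lgals7 (1.53-fold higher) and Cubn (1.61-fold higher). The lists of p53 targets (adjusted p = 0.560), NRF2 and antioxidant genes (0.136), 2-oxoglutarate dioxygenases (0.370), germline genes silenced by DNA methylation (0.582), matrix (0.103), senescence (0.941), endothelial (0.698), skeletal muscle (0.941), adipocyte (0.275), keratinocyte (0.318), erythroid (0.318) and early endoderm genes (0.159) had no call. The germline list had a mean log2 signal between 3.60 and 3.84 on every array, below the cut of 4.54 for dim genes, so its result decides little. Mean and median had opposite signs for the senescence (0.02 and -0.03) and endothelial lists (0.03 and -0.03). In the exact two-sided sign-flip permutation test over the 6 days, the pluripotency and interferon means were higher, and the collagen modification, HIF, unfolded protein response and neural means lower, on 6 of 6 days (p = 0.03125, the smallest possible). After adjustment over 23 lists none passed (adjusted p = 0.120).

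**Figure D3:**
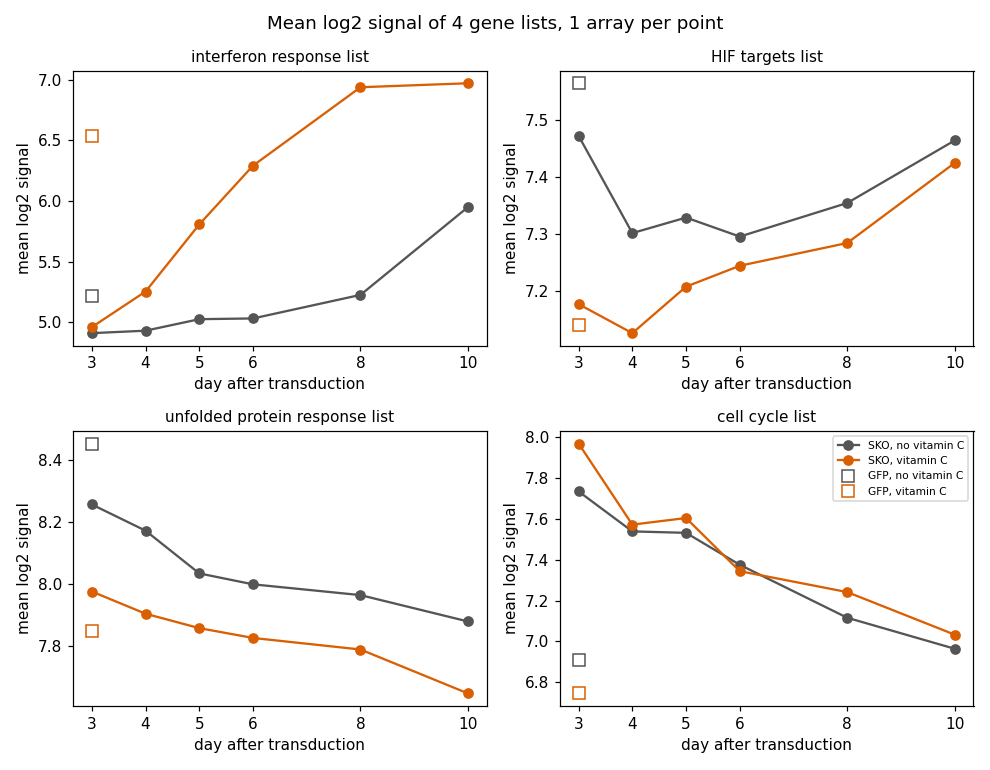
Mean log2 signal (vertical axis) of the interferon response, HIF target, unfolded protein response and cell cycle lists on each array against the day after transduction (horizontal axis); circles joined by lines are SKO cells, open squares GFP cells, orange with and grey without vitamin C. The interferon mean reached 6.97 with vitamin C on day 10 against 5.95 without, and the unfolded protein response mean was lower with vitamin C on all 6 days.

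In all, 128 genes were higher and 58 lower with vitamin C among 19938 tested (limma with the day as a factor, adjusted p under 0.05). The count was 66 without day 5, 23 without day 6, 46 without day 8 and 71 without day 10. It was 0 within days 3, 5 and 10 (limma, 1560 at an unadjusted p under 0.05) and 62 within days 4, 6 and 8, with 3 day pairs each. Without pairing the arrays by day it was 4. The interferon mean was 0.62 and 1.10 within the 2 sets of days, the unfolded protein response mean -0.23 and -0.21, and the HIF mean -0.15 and -0.10.

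Whether the vitamin C difference itself changed over the days was tested as a slope per day. Itga4, an integrin gene, fell by 0.38 ± 0.04 (SE) per day relative to untreated cells (adjusted p = 0.00823), from a difference of 1.27 on day 3 to -1.23 on day 10. Akr1c18 (-0.30 per day), Csn1s1, a casein gene (-0.34), Gpr50 (-0.48) and Kcnh5 (-0.29) fell as well, whereas Slfn2 (0.33) and Plac8 (0.31) rose. These were the 7 genes past the test. Larger slopes that did not pass included Cfb (0.50, adjusted p = 0.0628), Ddx60 (0.40), Ifit3 (0.39), Usp18 (0.38), Iigp1 (0.37) and Sp100 (0.34) upward, and Tslp (-0.39), Prss3 (-0.37) and Npy2r (-0.36) downward. The interferon response list had a mean slope of 0.17 per day with 0 of 36 past the test and 13 when adjusted over the list alone (camera adjusted p = 4.64e-23, and 0.442 with an estimated correlation). HIF targets (0.03 per day, adjusted p = 0.00335), NRF2 and antioxidant genes (0.03, 0.00545) and cholesterol synthesis genes (-0.05, 0.00108) also had calls, as had keratinocyte (-0.04, 0.0459) and matrix genes (0.03, 0.0493), all lost with an estimated correlation (adjusted p between 0.430 and 0.614). The HIF slope was the shrinking of a negative difference. It was -0.30 on day 3, -0.18 on day 4, -0.12 on day 5, -0.05 on day 6, -0.07 on day 8 and -0.04 on day 10. No pluripotency or epithelial gene passed, with Nanog at 0.21 per day (adjusted p = 0.218). The count of genes was 0 without day 3 (limma, 1278 at an unadjusted p under 0.05), 1 without day 4, 1 without day 6, 3 without day 8 and 0 with the alternation score as a covariate.

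GFP cells showed whether the vitamin C difference was also present without the 3 factors. Of the 186 genes that differed in SKO cells, 137 (73.7%) had the same direction in the GFP pair of day 3, against 56.0% of all genes, namely 95 of the 128 higher and 42 of the 58 lower genes. In the GFP pair of day 3 the list means differed by 1.32 for the interferon response, -0.60 for the unfolded protein response, -0.42 for HIF targets, 0.68 for cholesterol synthesis and -0.16 for the cell cycle, against 0.05, -0.28, -0.30, 0.09 and 0.23 in the SKO pair of day 3. The test of the difference set this GFP pair against the mean of the SKO pairs over 6 days, so it mixes the virus with the day. It also assumes that 1 GFP pair varies like the SKO pairs. No gene passed it (limma, 0 of 19938; 1377 at an unadjusted p under 0.05), nor against the SKO pair of day 3 alone (0; 917 at an unadjusted p under 0.05), a fit added after the data were seen. The largest differences, none past the test, were 2.03 for the interferon-induced chemokine gene Cxcl10, 1.89 for Mmp3, 1.88 for Ifi203, 1.82 for Cd55, 1.69 for Dcpp3 and 1.66 for Ibsp, and -2.25 for Slc7a3, -1.88 for Car6, -1.83 for the cystine transporter gene Slc7a11, -1.73 for Cth, -1.69 for Trib3 and -1.59 for Clec3b. Against the SKO mean over the days, the vitamin C difference of the GFP pair was 0.59 higher for the cholesterol synthesis list (camera adjusted p = 2.17e-12, and 0.323 with an estimated correlation) and stood at -0.30 for the HIF list (7.92e-06, and 0.323). The unfolded protein response list stood at -0.39 (7.92e-06, and 0.083 with an estimated correlation) and the cell cycle list at -0.25 (7.92e-06, and 0.323). The interferon list stood at 0.47 (0.000148, and 0.586 with an estimated correlation). The 2-oxoglutarate dioxygenase (-0.17), neural (0.25), senescence (0.20), matrix (0.14) and early endoderm lists (0.18) had calls with adjusted p between 0.00703 and 0.0412, and between 0.323 and 0.586 with an estimated correlation. Against the SKO pair of day 3 alone, the interferon (1.27, 2.03e-21), cholesterol synthesis (0.58, 3.72e-09), cell cycle (-0.40, 6.25e-09), unfolded protein response (-0.32, 0.000669), senescence (0.25, 0.0156) and matrix lists (0.22, 0.0227) had calls, again lost with an estimated correlation (adjusted p between 0.172 and 0.553). The HIF list (-0.13, adjusted p = 0.176), the 2-oxoglutarate dioxygenase (-0.13, 0.165), neural (0.14, 0.197) and early endoderm lists (0.16, 0.187) had none.

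The position of treated arrays along the time course was measured over all genes, by setting each day's vitamin C difference against the change per day on the other 5 days. That change was fitted to the mean of both arms, so a vitamin C difference that grows over the days is partly built into it. A course of the untreated arrays alone was not fitted, so the values below are not progress along it. Treated arrays lay ahead of untreated arrays of the same day by 0.99 ± 0.76 days (mean ± SD over 6 days, 6 of 6 days ahead, exact two-sided sign-flip permutation p = 0.03125, the smallest possible). The lead was 0.25 days on day 3, 0.88 on day 4, 1.06 on day 5, 1.45 on day 6, 2.15 on day 8 and 0.13 on day 10. Without the interferon response genes it was 0.92 days (p = 0.03125 in the same exact test), and without the genes past the vitamin C test it was 0.75 days (5 of 6 days, exact p = 0.0625). Without day 10 it was 0.56 days, and without day 8 it was 0.65 days with 4 of 5 days ahead. It was 0.41 days within days 3, 5 and 10, with 2 of 3 days ahead, and 0.66 days within days 4, 6 and 8, with 3 of 3.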

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

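The test that reorders the days was chosen after the result was seen. Among 36 groups of 6 values (array summaries, daily list differences and the lead along the time course), 1 had a value far from the others; chance gives about 1 in 20. The collagen modification list differed by -0.00616 between the arms on day 6, against -0.17 to -0.23 on the other 5 days.

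The vitamin C difference changed over the days for 7 genes by the test of the slope. Itga4 (-0.38 per day, adjusted p = 0.00823) went from 1.27 on day 3 to -1.23 on day 10 and Akr1c18 (-0.30) from 1.41 to -0.70. Gpr50 (-0.48) went from 0.25 to -2.78, Csn1s1 (-0.34) from 0.03 to -2.56 and Kcnh5 (-0.29) from 0.34 to -1.92. Plac8 (0.31) went from -0.24 to 1.91 and Slfn2 (0.33) from -0.54 to 1.58. When the order of the 6 daily differences was changed, which keeps each gene's mean difference, 3 of 100 orders gave as many genes, the real one included, and the highest of the others gave 12. That share is small, but only 100 orders were drawn and the test was chosen after the result was seen, so chance is not excluded for the count. Leaving out day 3 gives 0 genes. Swapping the arms within days decides nothing here, because it adds each gene's mean difference to the spread; there 1 of 32 assignments, the real one, gave as many genes, and the highest of the others gave 3.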

How the results depend on the processing

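Fits within sets of days, without pairs of days, against day 4 or day 5 against SKO day 3 alone and with the alternation score were chosen after the data were seen. The vitamin C count of 186 was 364 with an intensity trend, 123 with a 1.5-fold minimum, 112 with the day as a line, 4 without the day in the model, that is, without the replicate block, 11 without days 4 and 10, 162 without days 3 and 5 and 129 with the score as a covariate. It was 0 within days 3, 5 and 10 and 62 within days 4, 6 and 8, which have fewer arrays, and leaving out 1 day gave 23 to 263. Day 10 against day 3 (2430) gave 964 to 2696 when a day or array was left out, 345 with day 5 and 3182 with day 4 as the base. Any day (3773) gave 1991 to 4323 without 1 day, 1107 without days 3 and 5, 1232 within days 3, 5 and 10 and 175 within days 4, 6 and 8. The slope count of 7 was 21 after median centring, 23 without dim genes, 35 with a trend, 0 with a 1.5-fold minimum per day, 0 with the score and 0 to 10 without 1 day. SKO against GFP (3519) gave 1551 against SKO day 4, 17 with the score, and 1298 to 3951 without 1 day or array. The test of GFP against SKO cells gave 1 gene with a trend and 0 otherwise. The lead of 0.99 days was 0.75 (exact p = 0.0625) without the genes past the vitamin C test and 0.56 to 1.11 without 1 day. Against day 4 Pou5f1 turned to -0.22 on day 10, and with the score as a covariate Tet3 (0.30), Thy1 (0.57) and Col1a1 (0.11) turned positive in SKO against GFP. Where fewer arrays do not show the cause, the cause was not tested. Of the other values, 3284 for named genes kept direction and side of the threshold, 241 lost the call and 27 gained one; for gene list tests these counts were 270, 64 and 11, and for daily list means 247, 5 and 1. With 1 array per condition and day, the number of arrays limits all of these tests, and signal over background was not measured.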

Other observations

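Single members passed the test in lists that had no call. Among senescence and secretory genes members passed in both directions by day 10, with Mmp3 8.56-fold and Ccl8 6.60-fold higher and Plaur 2.97-fold lower (5 of 36 higher, 3 lower; camera adjusted p = 0.190). Among HIF targets Aldoc rose 5.19-fold, Ak4 3.29-fold and Egln3 2.46-fold (7 of 37 higher, 2 lower, list mean 0.12 and median -0.04; adjusted p = 0.427). Among antioxidant genes Slc7a11 rose 2.76-fold and Nqo1 fell 2.57-fold (6 of 35 higher, 7 lower; adjusted p = 0.404). Of 27 germline genes that DNA methylation keeps silent, 0 passed from day 3 to day 10 (adjusted p = 0.710) and 0 passed for vitamin C. Their mean log2 signal was between 3.60 and 3.84 on every array, below the cut of 4.54 for dim genes. A change of these genes could thus be understated or missed, and the counts of 0 decide little. Adipocyte Lpl rose 4.35-fold, keratinocyte Trp63 1.78-fold and endothelial Ramp2 2.41-fold by day 10, and skeletal muscle Des fell 2.55-fold, in lists without a call.

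For the patterns below, the GFP test of the HIF targets, the tests of a shared handling day and of an unrecorded batch and the 3 tests of the interferon genes were chosen after the result was seen. Other splits of the 12 SKO arrays were counted for the vitamin C genes: of 100 splits into 6 and 6, the real one was 1 that gave 186 genes, and the highest of the others gave 23. A split that puts both arrays of a day in 1 arm loses that day pair, so it can find fewer genes for that reason alone. That comparison is thus unequal and decides nothing. When the arms were swapped within days, the real assignment was 1 of 32, and the highest of the others gave 0 genes. The swaps, which keep the day pairs, thus argue against chance for the count, at the smallest share that 32 assignments allow.

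Days 3 and 5 of the SKO cells stood apart from days 4 and 6; on the score made from these days, day 10 lay with days 3 and 5, and day 8 and the GFP arrays with days 4 and 6. Noise of single arrays is argued against by the r of 0.663 across genes between the alternation of the 2 arms, which share no array. A handling effect shared by all cells lysed on 1 day stays open: 2 of 2 GFP arrays of day 3 lay nearer to SKO day 4 than to SKO day 3, but GFP and SKO cells also differ by virus, so this decides nothing. A difference in cell division may contribute: the cell cycle list had a mean alternation of -0.13, at percentile 1.04 of matched random lists. The cholesterol synthesis (-0.22, percentile 0.72), collagen modification (0.24, 99.85) and epithelial lists (0.14, 99.5) also lay outside the central 95%, so the alternation was not particular to cell division. A labelling or array batch cannot be told apart from a change of the cells, because both would put the 2 arrays of a day on 1 side, as seen on 3 of the 3 day pairs not used to make the score (the others are fixed by its construction), and the labels name no batch.

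The interferon response list had a mean difference of 0.86 with vitamin C in SKO cells, from 0.05 on day 3 to 1.71 on day 8, with 13 of 36 past the test and 23 not; its call (camera adjusted p = 1.31e-32) was lost with an estimated correlation (adjusted p = 0.244), and the 1.32 of the GFP pair comes from 1 array against 1. A compressed range of values is argued against by the median of 0.006 in 10000 matched random lists, against 0.86 for the list (percentile 100). That percentile does not allow for members that vary together (estimated correlation 0.699). More macrophages in the treated cultures are argued against by the macrophage mean of 0.0376 ± 0.105 (SD over 6 days). It was -0.06 on day 6 and 0.20 on day 8, beside interferon differences of 1.26 and 1.71. The most abundant markers were Laptm5 (log2 signal 6.51, difference 0.11 ± 0.27, SD over the days), Cd68 (6.40, 0.04 ± 0.24), C1qa (6.04, -0.09 ± 0.10) and Lyz2 (5.75, -0.01 ± 0.50). Lyz2 varied widely between days, so it says little alone. None of the 23 markers is on another list. The split between arrays is argued against by the difference of 1.26 or more on days 6 and 8, where the treated array had the higher and then the lower score. A response to vitamin C and a response of these particular cultures both remain possible, since each condition was 1 culture series; this was not tested.

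The HIF list had a negative mean difference with vitamin C (-0.13, median -0.04), with 2 of 37 past the test, P4ha1 and P4ha2, which also belong to collagen modification; its call (camera adjusted p = 0.000936) was lost with an estimated correlation (adjusted p = 0.434). A compressed range is argued against by the median of -0.008 in 10000 matched random lists, against -0.13 for the list (percentile 0). That percentile does not allow for members that vary together (estimated correlation 0.117). The daily difference of the list mean went from -0.30 on day 3 to -0.04 on day 10. After quantile normalization 103% of the list mean remained. RMA in its standard form had already applied that step, so this decides nothing about a leftover of normalization. Whether the difference needs the 3 factors stays open: the GFP pair had a mean of -0.42, at percentile 0 of matched random lists, but this is 1 array against 1 and genes are not replicates. Whether it comes from vitamin C or from these particular cultures was not tested. The hydroxylases that limit HIF use vitamin C, but no measurement of HIF protein was used here.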
